A study of Homo sapiens with 6 samples.

How the data were processed

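The series holds 6 Affymetrix Human Genome U133 Plus 2.0 arrays of DLD1 cells, 3 exposed to vehicle and 3 to 10 µM SAH-BCL9B for 12 h. The labels describe the cultures as triplicates, and the group and replicate number of each array come from its title. Biotin-labelled cRNA was prepared with the GeneChip 3' IVT Express kit, per the labels' protocols.

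The authors deposited 1 table of log2 expression values, 54675 probe sets by 6 arrays. The submitters' processing notes name RMA and affy; versions and options are not given in the sources used here. RMA subtracts background, normalizes between arrays and summarises the probes of each probe set on the log2 scale. That the deposited values are log2 follows from their range, with a minimum of 3.26 to 3.35 and a maximum of 15.7 to 15.8 in each array and medians of 6.58 to 6.62. Quantile normalization makes arrays alike in distribution, so a change shared by most genes would not be seen. RMA also shrinks the changes of dim probe sets, so low genes are understated. Neither scanner files nor detection calls were used here, so signal over background is unknown.

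Probe sets were named through GEO's annotation of the platform, with symbols checked by Entrez ID against RefSeq genes of assembly GCF_000001405.40 (GRCh38.p14), used for names alone. Of the 54675 probe sets, 62 were array controls, 41091 named 1 gene, 1801 named several and 11721 were unnamed here. For 41037 of those naming 1 gene the Entrez ID matched, and 0 symbols needed an update. Each of 19775 genes was represented by 1 probe set, the one with the highest mean over the 6 arrays among those naming only that gene. In 10523 genes there was more than 1 to choose from. No filter on low values was set.

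Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, SAH-BCL9B minus vehicle, no covariates; prior degrees of freedom 3.94), with Benjamini-Hochberg adjustment over the 19775 genes and a threshold of 0.05. A further count required a difference of at least 1.5-fold. Errors of a log2 change are limma's moderated standard errors, and errors of a group mean are SDs over 3 arrays. The 24 gene lists were tested with camera, with a preset correlation between genes of 0.01 and adjustment over the 24 lists. Of these, 12 passed with the preset correlation and 0 with a correlation estimated per list; 11 of those 12 and the list of ribosomal proteins passed with fry. Tables were handled with the R package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15. Control probe sets gave the RNA quality values, compared by exact permutation tests.

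The tests, lists and alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. The rule named 11 genes of the pathway whatever their result (BCL9, BCL9L, CTNNB1, AXIN2, LGR5, MYC, CCND1, CD44, VEGFA, ASCL2 and NKD1). It also named the 10 raised and 10 lowered genes with the largest change among those past the threshold with no overlap of the groups, leaving out symbols that start with LOC or stand for open reading frames. In each list past the set test it named the 3 members with the largest change in the list's direction, and in other lists members past the threshold, at most 4. RNF43, CCNE1, SLC7A11, KLF6, FOSL1, IER3, SLC2A1, PLAUR and IFITM1 fell outside it and were chosen after their values were seen, to complete short counts. The values of 1 Wnt target gene that fell are not reported here, though the counts and list tests include it. The genes of the lists added in the closing section were chosen in that way too.

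The procedure was tested on simulated data with the real genes' means and spreads. Of 100 genes changed by 0.5 on the log2 scale among 19775, 37 were recovered, and of 100 changed by 1, 83, with 2 false calls. With no change there were 0 calls, and 0 of 50 unchanged lists passed. A difference of 0.5 or less that did not pass may therefore be real. The simulated genes varied independently of each other, so the result for lists says nothing about lists whose genes vary together.

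Alternatives covered the replicate number as a block, a filter that kept genes above the median level of all probe sets, other uses of several probe sets, median centring, a second quantile normalization, a variance trend with robust fitting, array weights and each array left out in turn. Added after seeing the data were the SD of each array's values and its ACTB 3' minus 5' difference as covariates, and a fit without vehicle 3 and SAH-BCL9B 2.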

Results

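Gene expression was measured in DLD1, an established human colorectal adenocarcinoma line, after 12 h with 10 µM SAH-BCL9B or with vehicle. SAH-BCL9B is a hydrocarbon-stapled peptide modelled on the part of BCL9 that binds beta-catenin, and the series title names disruption of the BCL9/beta-catenin complex as its subject. Each group had 3 arrays, from what the labels call triplicate cultures, so the 6 arrays allowed 1 comparison, SAH-BCL9B against vehicle. The values are log2 expression levels, and 19775 genes were measured by 1 probe set each. The number of arrays limits the precision, and every n below is 3 per group. The design held no control peptide.

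After 12 h with SAH-BCL9B, 12 of 24 gene lists differed from other genes in limma's camera test, and 0 did with a correlation between genes estimated per list (lowest adjusted p = 0.08 with an estimated correlation). The largest falls were in ID3, an inhibitor of basic helix-loop-helix transcription factors, which was 4.78-fold lower (log2 12.23 ± 0.05 in vehicle and 9.97 ± 0.15 in SAH-BCL9B, SD, n = 3), in the calmodulin-binding protein gene PCP4 (4.48-fold lower) and in the epithelial chloride channel gene CFTR (4.34-fold lower). SYTL5, S100P, CRTAM, FRMD3, NUPR1, PCK2 and FOXN1 completed the 10 largest falls, with log2 changes from -2.05 for SYTL5 to -1.66 for FOXN1. The largest rise was in ATP6V1C2, which encodes a subunit of the proton pump V-ATPase and was 3.43-fold higher (log2 9.46 ± 0.15 and 11.24 ± 0.11, SD, n = 3). The serine protease inhibitor gene SERPINI1 was 2.99-fold higher, the chemokine gene CXCL8 2.93-fold higher and the histone genes H2BC4 and H4C8 2.90-fold and 2.81-fold higher. CHRM3, AMACR, EID3, the ERK phosphatase gene DUSP5 and the aminopeptidase gene ENPEP followed, with log2 changes from 1.42 for CHRM3 to 1.07 for ENPEP. In limma's test with Benjamini-Hochberg adjustment, the adjusted p of these 20 genes ran from 0.000103 for ID3 and PCP4 to 0.0203 for ENPEP, and the rule that chose them required the 3 SAH-BCL9B arrays to lie beyond the 3 vehicle arrays. H2BC4 missed the threshold without vehicle 1 or SAH-BCL9B 3 (highest adjusted p = 0.069), and ENPEP without vehicle 1, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 3 (highest 0.09). The probe sets of CFTR did not all move together: 2 of its 6 went the opposite way, with log2 changes of up to 0.08. The same held for 1 of the 2 probe sets of FOXN1. With the mean of all probe sets of a gene, the change was -0.76 for CFTR, -1.11 for SYTL5, -0.79 for FOXN1, 0.61 for CHRM3 and 0.54 for AMACR. All 5 passed in every alternative that tested them (highest adjusted p = 0.0049, 0.0083, 0.016, 0.024 and 0.018). The filter on low values left out FOXN1 and ENPEP. Vehicle means of CHRM3 (log2 5.99), ENPEP (6.01), EID3 (6.22) and H4C8 (6.53) lay below the array medians of 6.58 to 6.62. So did the SAH-BCL9B means of FOXN1 (5.475), SYTL5 (6.36) and CRTAM (6.40). Signal over background is unknown, so the size of these changes is uncertain.

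**Figure D1:**
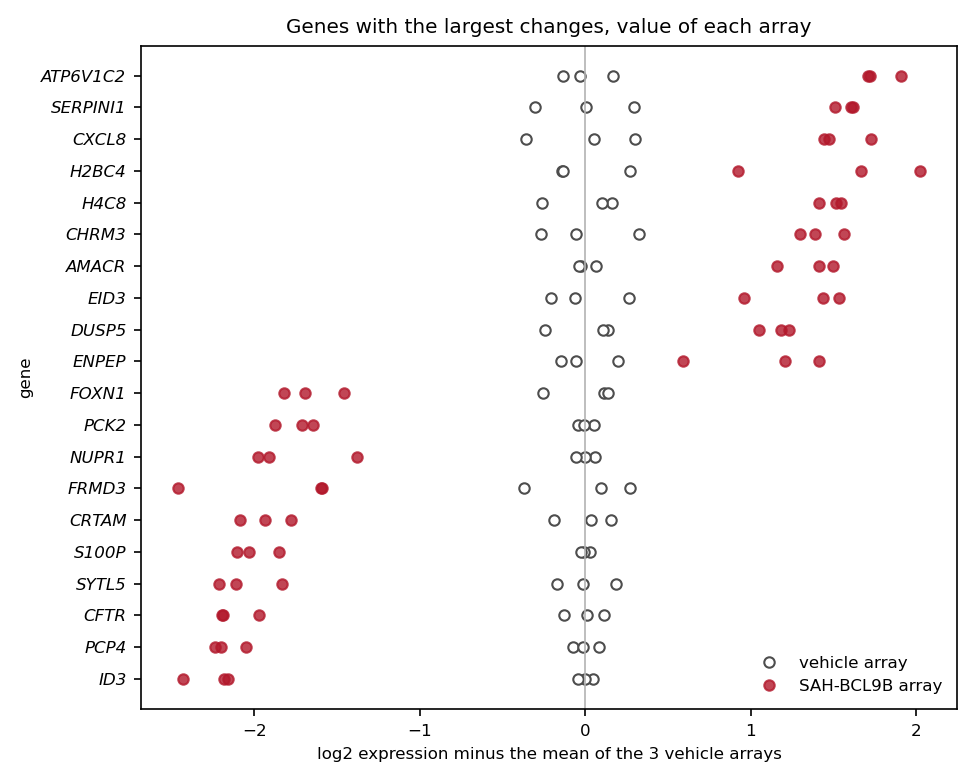
Log2 expression of each array minus the mean of the 3 vehicle arrays, for the 10 genes with the largest rises and the 10 with the largest falls. Open points are the vehicle arrays and filled points the SAH-BCL9B arrays, and in all 20 genes the groups do not overlap.

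Over all genes, 1370 of 19775 passed an adjusted p of 0.05 in limma's test (6.93%), 691 of them higher and 679 lower in SAH-BCL9B. Of these, 405 differed by at least 1.5-fold, 144 upward and 261 downward, and 55 by at least 2-fold, 15 upward and 40 downward. The groups did not overlap in 5599 genes (28.3%), against 10% by chance, and all 1370 were among them. The median log2 change of all genes was 0.02. The number of genes past the threshold fell to 316 without vehicle 1, 518 without vehicle 2, 692 without vehicle 3, 514 without SAH-BCL9B 1 and 522 without SAH-BCL9B 3, and was 1426 without SAH-BCL9B 2.

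Genes that beta-catenin and its TCF partners are known to activate were lower as a group. Of 27 measured Wnt/beta-catenin target genes, 6 fell, none rose and 21 did not pass the test, and 19 of the 27 had a negative change (median log2 change -0.18). Adjusted over the list alone, 10 were lower and 1 was higher. The angiogenic growth factor gene VEGFA fell most, 2.09-fold (log2 change -1.06 ± 0.08, SE, limma adjusted p = 0.000963), in all 4 of its probe sets. The adhesion receptor gene CD44 changed by -0.66 ± 0.11, and ASCL2, a transcription factor of intestinal stem cells, by -0.52 ± 0.07 (adjusted p = 0.0128 and 0.008). RNF43, which encodes a negative regulator of Wnt receptors, changed by -0.48 ± 0.08, and AXIN2, a widely used readout of the pathway, by -0.40 ± 0.10 (adjusted p = 0.0151 and 0.047). The set test, camera, gave the list an adjusted p of 3.8e-05, and the adjusted p = 0.12 with an estimated correlation between genes. AXIN2 missed the threshold without any 1 of the 6 arrays (adjusted p = 0.061 to 0.18), and with the mean of all probe sets, every probe set tested by itself, median centring, the ACTB covariate or vehicle 3 and SAH-BCL9B 2 left out (range over the alternatives 0.0025 to 0.18). CD44 missed it without vehicle 1, SAH-BCL9B 1 or SAH-BCL9B 3 (highest adjusted p = 0.067), ASCL2 without vehicle 1 (0.052), and RNF43 without vehicle 1, vehicle 2, vehicle 3 or SAH-BCL9B 3 (highest 0.071). With the replicate number as a block, AXIN2, CD44 and ASCL2 also missed the threshold (limma adjusted p = 0.11, 0.058 and 0.055). The number of targets that fell was 2 without vehicle 1 and 3 without SAH-BCL9B 3. Of the 13 probe sets of CD44, 3 went the opposite way, and the mean of all 13 gave -0.27 and missed the threshold (adjusted p = 0.062, range 0.00096 to 0.067 over the alternatives).

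Other well-known targets did not pass the test. The log2 change was -0.27 ± 0.08 (SE) for the stem cell marker LGR5 (limma adjusted p = 0.0928), 0.31 ± 0.09 for MYC (0.0882), 0.15 ± 0.09 for CCND1, which encodes cyclin D1 (0.428), and -0.18 ± 0.08 for NKD1 (0.246). LGR5 and MYC passed it with a filter on low values (adjusted p = 0.038 for each), with a variance trend and robust fit (0.032 and 0.0093) and with array weights (0.03 and 0.045), in the same directions. Over all alternatives the adjusted p ran from 0.03 to 0.27 for LGR5 and from 0.0093 to 0.29 for MYC. The 2 probe sets of CCND1 had opposite signs, and the mean of both gave -0.02 (adjusted p = 0.98, range 0.16 to 0.98 over the alternatives). The transcripts of the complex itself did not pass either: the change was 0.11 ± 0.08 for BCL9, 0.15 ± 0.10 for its paralog BCL9L and 0.15 ± 0.07 for CTNNB1, which encodes beta-catenin (adjusted p = 0.523, 0.466 and 0.306). Of the probe sets of BCL9L and CTNNB1, 1 each went the opposite way. None of 25 beta-catenin complex and Wnt pathway component genes passed, over all genes or adjusted over the list alone, and their median was 0.01 (camera adjusted p = 0.89). With every probe set tested by itself, 1 of the 7 probe sets of TCF7L2 passed, downward, and none of the 7 went the opposite way. So did 1 of the 13 of CSNK1A1, of which 4 went the opposite way.

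**Figure D2:**
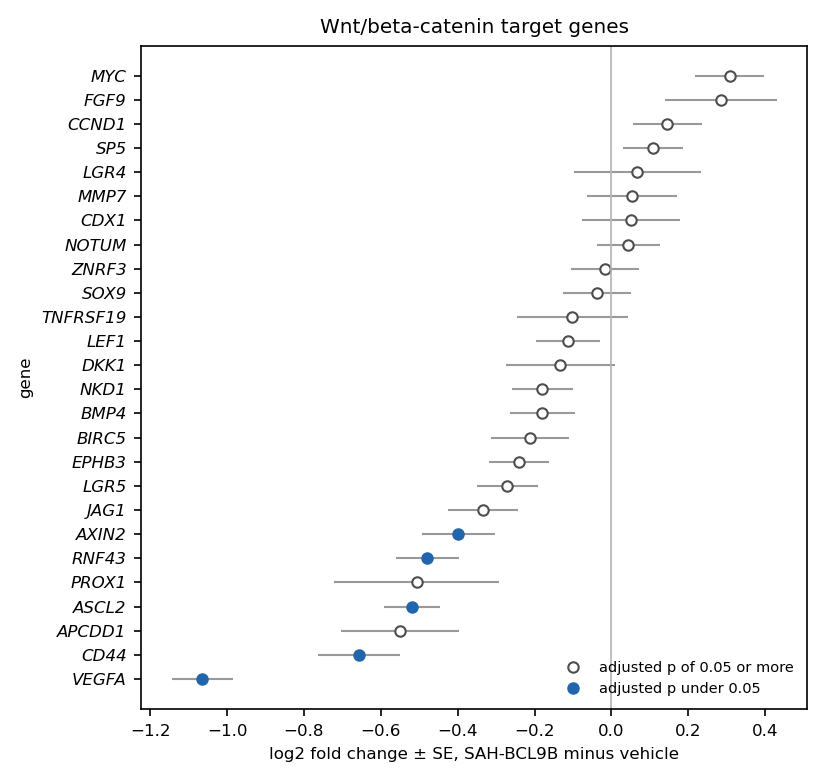
Log2 fold change of 26 of the 27 measured Wnt/beta-catenin target genes, SAH-BCL9B minus vehicle, with bars of 1 SE. Filled points have an adjusted p under 0.05: 5 genes, all lower, from VEGFA at -1.06 to AXIN2 at -0.40, while MYC lies at 0.31.

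Genes of the G2 phase and mitosis were lower. All 26 measured members had a negative change (median -0.42), 15 fell and none rose (18 lower and 0 higher adjusted over the list alone). The kinetochore gene CENPF changed by -0.70 ± 0.07 (SE) and the spindle-associated gene HMMR by -0.68 ± 0.09 (limma adjusted p = 0.00309 and 0.00587). TOP2A, which encodes a topoisomerase, had a value of -0.81 ± 0.34 and did not pass the test (adjusted p = 0.218). Its value was -0.36 without SAH-BCL9B 2, -0.40 without that array and vehicle 3, -0.32 with the ACTB covariate and -0.31 with the mean of all probe sets. It passed with array SD as a covariate (adjusted p = 0.032, range 0.032 to 0.52 over the alternatives), and 1 of its 3 probe sets went the opposite way. With camera the list had an adjusted p of 3.5e-16, and the adjusted p = 0.08 with an estimated correlation. The number of members that fell was 5 without vehicle 1, vehicle 2 or SAH-BCL9B 1, and 7 without vehicle 3 or SAH-BCL9B 3.

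Genes of the G1/S transition and DNA replication moved less. Of 24 measured members, 6 fell and 1 rose (8 lower and 3 higher adjusted over the list alone), and the median change was -0.06. The replication factor gene CDC45 changed by -0.51 ± 0.11 (SE), and the helicase genes MCM7 and MCM2 by -0.44 ± 0.07 and -0.39 ± 0.07 (limma adjusted p = 0.0322, 0.0134 and 0.0197). The member that rose was the cyclin gene CCNE1 (0.42 ± 0.08, adjusted p = 0.0194). With the mean of all probe sets the median was -0.10, and without SAH-BCL9B 3 it was -0.10 too. The camera adjusted p of the list was 0.047, and the adjusted p = 0.5 with an estimated correlation. The list missed the threshold without vehicle 1, vehicle 2, SAH-BCL9B 1 or SAH-BCL9B 2 (highest adjusted p = 0.21). It also missed it with fry (adjusted p = 0.052), the filter on low values (0.065), the replicate number as a block (0.067) and array SD as a covariate (0.069). The same held for array weights (0.088), the ACTB covariate (0.29) and vehicle 3 and SAH-BCL9B 2 left out (0.14). The list's adjusted p ran from 0.0097 to 0.5 over the alternatives. No member fell without vehicle 1, vehicle 2, SAH-BCL9B 1 or SAH-BCL9B 3, and 1, MCM7, fell without vehicle 3 (highest adjusted p = 0.13 for CDC45, 0.072 for MCM7 and 0.087 for MCM2). CCNE1 missed the threshold without every array except SAH-BCL9B 2 (highest 0.081).

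Genes of the unfolded protein response and of ATF4, the transcription factor of amino acid stress, were lower. Of 24 measured members, 13 fell and none rose (14 lower and 2 higher adjusted over the list alone), with a median change of -0.38. The lipoprotein receptor gene VLDLR changed by -1.44 ± 0.11 (SE), ASNS, which encodes asparagine synthetase, by -1.08 ± 0.08, and DDIT4, an inhibitor of mTOR signalling, by -1.05 ± 0.08 (limma adjusted p = 0.000963, 0.000739 and 0.00103). Split after the values were seen, the 9 members linked to endoplasmic reticulum chaperones and to XBP1 or ATF6 had a median of 0.001 with 2 lowered. The other 15, linked to ATF4, had a median of -0.81 with 11 lowered. The camera adjusted p of the whole list was 1.4e-09, and the adjusted p = 0.12 with an estimated correlation. NUPR1 and PCK2, among the 10 largest falls, are also known to respond to ATF4.

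Intestinal differentiation genes were lower as a list, although few passed singly. Of 24 measured members, 2 fell and none rose (3 lower and 0 higher adjusted over the list alone), and the median was -0.13. These were VIL1, which encodes the microvillus protein villin (-0.86 ± 0.09, SE, limma adjusted p = 0.00303), and the mucin gene MUC13 (-0.58 ± 0.08, adjusted p = 0.00803). CEACAM6 followed with -0.49 ± 0.13 and did not pass (adjusted p = 0.0699), though it passed with a variance trend and robust fit (0.047) and with array SD as a covariate (0.033; range 0.033 to 0.18 over the alternatives). The list's camera adjusted p was 0.00057, and the adjusted p = 0.083 with an estimated correlation. MUC13 missed the threshold without vehicle 1 (adjusted p = 0.051), which left 1 member that fell. With the mean of all probe sets the change was -0.40 for VIL1 and -0.34 for MUC13 (adjusted p = 0.019 and 0.031).

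Heat shock and oxidative stress genes were higher. Of 14 measured heat shock genes, 8 rose and none fell (10 and 0 adjusted over the list alone), with a median change of 0.37. The cochaperone genes DNAJA1 and DNAJB1 rose by 1.02 ± 0.08 and 0.82 ± 0.07 (SE), and the chaperone gene HSPA4L by 0.70 ± 0.08 (limma adjusted p = 0.000963, 0.00137 and 0.00344). For heat shock genes the camera adjusted p was 1.2e-07, and the adjusted p = 0.08 with an estimated correlation. Of 17 measured targets of the oxidative stress factor NRF2, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.24. SRXN1, which encodes sulfiredoxin, rose by 0.76 ± 0.08, GCLM, of glutathione synthesis, by 0.66 ± 0.07, and the quinone reductase gene NQO1 by 0.54 ± 0.07 (adjusted p = 0.00315, 0.00344 and 0.00774). The member that fell was the cystine transporter gene SLC7A11 (-0.81 ± 0.08, adjusted p = 0.0028), which the ATF4 list also holds. For NRF2 targets it was 0.0024, and the adjusted p = 0.18 with an estimated correlation. With the mean of all 3 probe sets GCLM missed the threshold (0.54, adjusted p = 0.085, range 2.9e-05 to 0.085 over the alternatives). The number of heat shock genes that rose was 3 without vehicle 1, vehicle 2, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 3. The number of NRF2 targets that rose was 3 without any 1 of the 6 arrays.

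Sterol and lysosome genes were higher too. Of 16 measured genes of cholesterol synthesis and uptake, 7 rose and none fell (9 and 0 adjusted over the list alone), with a median of 0.31. IDI1, an isomerase of the mevalonate pathway, rose by 0.62 ± 0.09 (SE), INSIG1, the sterol-sensing regulator of the pathway, by 0.53 ± 0.10, and DHCR7, which acts in a late step of cholesterol synthesis, by 0.51 ± 0.11 (limma adjusted p = 0.00833, 0.0199 and 0.0313). For sterol genes the camera adjusted p was 3.1e-07, and the adjusted p = 0.083 with an estimated correlation. Of 21 measured lysosome and autophagy genes, 8 rose and none fell (12 and 0 adjusted over the list alone), with a median of 0.26. NEU1, which encodes a lysosomal sialidase, rose by 0.92 ± 0.08, the autophagy receptor gene SQSTM1 by 0.91 ± 0.07 and the autophagy gene WIPI1 by 0.70 ± 0.12 (adjusted p = 0.00137, 0.00103 and 0.0134). Of the 5 probe sets of SQSTM1, 2 went the opposite way, and the mean of all 5 gave 0.46 (adjusted p = 0.025). The mean of the probe sets of IDI1 gave 0.39 (adjusted p = 0.022). For lysosome and autophagy genes it was 9.7e-08, and the adjusted p = 0.16 with an estimated correlation. INSIG1 and DHCR7 missed the threshold without vehicle 1, vehicle 2, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 3 (highest adjusted p = 0.098 and 0.13), and WIPI1 without vehicle 1, SAH-BCL9B 1 or SAH-BCL9B 3 (highest 0.068). The number of sterol genes that rose was 1 without vehicle 1, 2 without vehicle 2 or SAH-BCL9B 3 and 3 without vehicle 3 or SAH-BCL9B 1. For lysosome and autophagy genes it was 2 without vehicle 1 or SAH-BCL9B 1, 3 without vehicle 2, 4 without vehicle 3 and 5 without SAH-BCL9B 3.

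Inflammatory, metallothionein and histone genes were also higher. Of 20 measured NF-kappaB and inflammatory genes, 7 rose and none fell (7 and 0 adjusted over the list alone), with a median of 0.18. CXCL8 rose by 1.55 ± 0.17 (SE), the chemokine gene CXCL2 by 0.87 ± 0.13 and RELB, an NF-kappaB subunit gene, by 0.82 ± 0.09 (limma adjusted p = 0.00314, 0.00877 and 0.00314). For inflammatory genes the camera adjusted p was 0.0012, and the adjusted p = 0.083 with an estimated correlation. Of 11 measured metallothionein and metal response genes, 6 rose and none fell (6 higher and 2 lower adjusted over the list alone), with a median of 0.44. MT2A, MT1X and MT1F rose by 0.69 ± 0.09, 0.68 ± 0.10 and 0.59 ± 0.07 (adjusted p = 0.00509, 0.0095 and 0.00507). These genes are near-identical in sequence, and their probe sets may not tell them apart. For the metallothionein list it was 0.0013, and the adjusted p = 0.18 with an estimated correlation. Of 7 measured histone genes in a list of RNA quality and short-lived histone mRNAs, 6 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.74. H4C8 rose by 1.49 ± 0.12, and H2AC6 and H2BC5 by 0.83 ± 0.11 and 0.83 ± 0.09 (adjusted p = 0.00109, 0.00555 and 0.0028). Histone genes also share sequence. For the histone list it was 8.6e-08, and the adjusted p = 0.083 with an estimated correlation. The median of the inflammatory list was 0.43 with the filter on low values and ran from 0.129 to 0.426 over the alternatives, and CXCL2 changed by 0.46 with the mean of its probe sets. MT1X missed the threshold without vehicle 1 (adjusted p = 0.053). The number of inflammatory genes that rose was 3 without vehicle 1 and 4 without vehicle 2 or SAH-BCL9B 1, and that of metallothionein and metal response genes was 2 without vehicle 1.

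**Figure D3:**
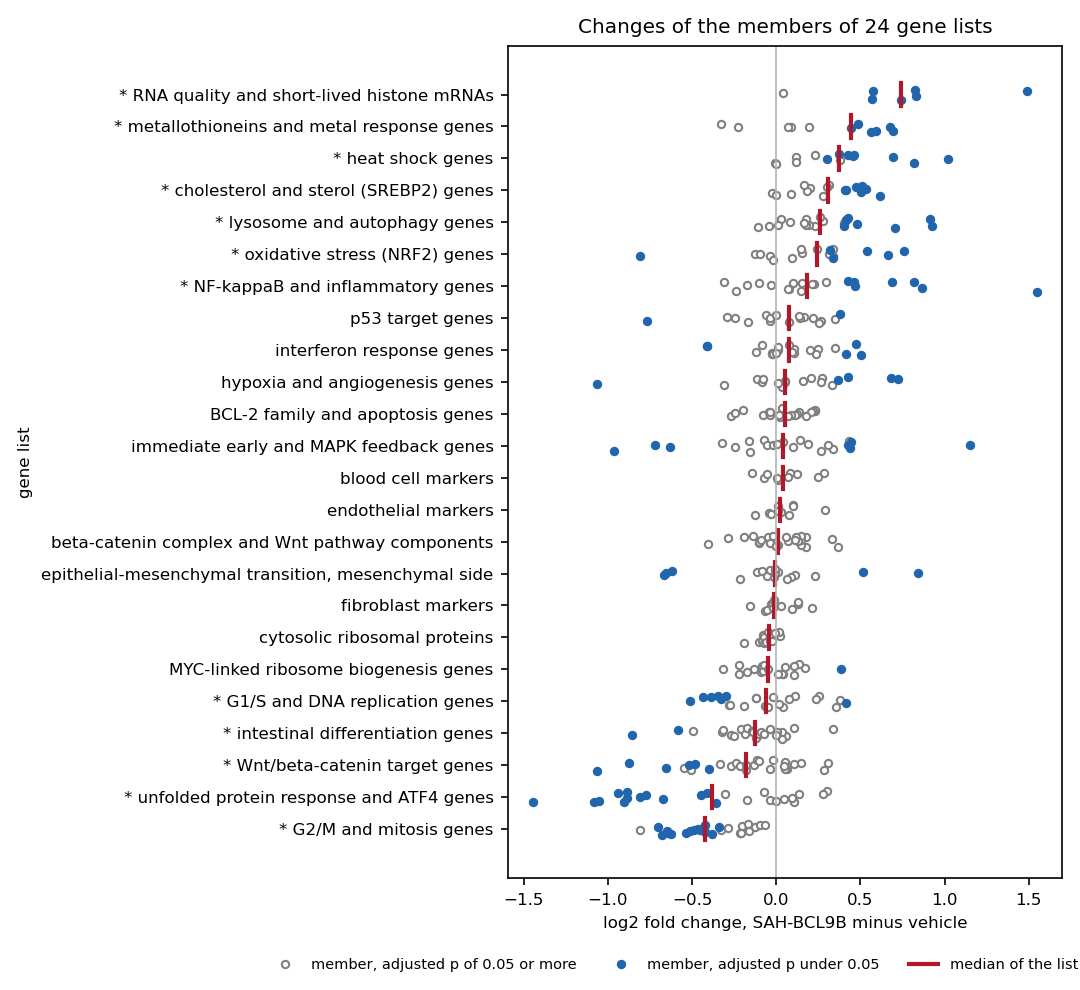
Log2 fold change of each measured member of the 24 gene lists, SAH-BCL9B minus vehicle, with the median of each list as a red bar. Filled points have an adjusted p under 0.05 over all genes, and an asterisk marks the 12 lists with a camera adjusted p under 0.05, whose medians run from -0.42 for G2/M and mitosis genes to 0.74 for the histone genes.

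Members of several other lists moved in both directions, and these lists did not pass the set test. Among 23 immediate early and MAPK feedback genes, 4 rose and 3 fell (8 and 5 adjusted over the list alone, median 0.04, camera adjusted p = 0.75). DUSP5 rose by 1.15 ± 0.12 (SE), KLF6, FOSL1 and IER3 by 0.44, 0.44 and 0.43, while the AP-1 genes FOSB and FOS changed by -0.96 ± 0.14 and -0.63 ± 0.08 and the MAPK inhibitor gene SPRY4 by -0.72 ± 0.10. Among 19 hypoxia and angiogenesis genes, 4 rose and only VEGFA fell (6 and 1 adjusted over the list alone, median 0.05, camera adjusted p = 0.1). These 4 were the vasodilator peptide gene ADM (0.73 ± 0.09), the prolyl hydroxylase gene P4HA2 (0.68 ± 0.09), ANKRD37 (0.43 ± 0.09) and the glucose transporter gene SLC2A1 (0.37 ± 0.09). Of the 3 probe sets of P4HA2, 2 went the opposite way, and the mean of all 3 gave 0.15 (adjusted p = 0.32, range 0.00012 to 0.32 over the alternatives). The number of hypoxia genes that rose was 2 without vehicle 1, vehicle 2, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 2. Among 18 mesenchymal genes of the epithelial-mesenchymal transition, TGFB1 (0.84 ± 0.13) and the urokinase receptor gene PLAUR (0.52 ± 0.07) rose, and S100A4, CD44 and TGFBI fell, by 0.67, 0.66 and 0.62 on the log2 scale (2 higher and 3 lower adjusted over the list alone, median -0.01, camera adjusted p = 0.48). ANKRD37 missed the threshold without vehicle 1, vehicle 2, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 2 (highest adjusted p = 0.14), SLC2A1 without any 1 array (highest 0.2) and TGFB1, for which 1 of 2 probe sets went the opposite way, without vehicle 1 or SAH-BCL9B 1 (highest 0.059), and the mean of both gave 0.36. ANKRD37 also missed it with the mean of its probe sets (0.29, adjusted p = 0.12). FOSL1 and IER3 missed it without vehicle 1, vehicle 2, vehicle 3, SAH-BCL9B 1 or SAH-BCL9B 3 (highest 0.14 and 0.11), and KLF6 without vehicle 1, vehicle 2, SAH-BCL9B 1 or SAH-BCL9B 3 (highest 0.09).

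Interferon and p53 target genes moved in both directions, and no apoptosis gene passed. Among 21 interferon response genes, IRF9, ISG15 and IRF1 rose by 0.50, 0.47 and 0.42, and MX1 and IFITM1 both fell by 0.41 on the log2 scale (5 higher and 2 lower adjusted over the list alone, median 0.07, camera adjusted p = 0.3). IRF1 missed the threshold without any 1 array (highest adjusted p = 0.15) and with the mean of its probe sets (0.13), and IRF9 without 5 of them (highest 0.14), all except SAH-BCL9B 3. MX1 and IFITM1 missed it without every array except SAH-BCL9B 2 (highest 0.13 and 0.14), and ISG15 without vehicle 1 or vehicle 2 (highest 0.071). Among 17 p53 target genes, the DNA repair gene DDB2 fell by 0.77 (SE 0.08, limma adjusted p = 0.00296) and TIGAR rose by 0.38 (SE 0.09, adjusted p = 0.0432), with 2 lower and 2 higher adjusted over the list alone (median 0.08, camera adjusted p = 0.97). TIGAR missed the threshold without every array except SAH-BCL9B 2 (highest 0.18), and 3 p53 targets rose without that array. None of 20 BCL-2 family and apoptosis genes passed, over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.63). With every probe set tested by itself, 1 of the 7 probe sets of BCL2L11 passed, upward.

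Ribosome genes did not differ from other genes in the camera test. Of 19 ribosome biogenesis genes linked to MYC, POLR1A alone passed (0.38 ± 0.09, SE, limma adjusted p = 0.0409), and it missed the threshold without any 1 array (highest adjusted p = 0.17). Its 3 probe sets included 1 with the opposite sign, and their mean gave 0.12 (adjusted p = 0.48). The list's median was -0.05 (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.52). None of 16 cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (median -0.04, camera adjusted p = 0.11), while fry, which tests whether the genes move one way on balance, gave an adjusted p of 0.034. With every probe set tested by itself, 1 of the 2 probe sets of RPS23 passed, downward.

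Markers of cells that a DLD1 culture should not hold did not pass, over all genes or adjusted over their lists alone. The median change was -0.015 for 12 fibroblast markers, 0.04 for 10 blood cell markers and 0.02 for 10 endothelial markers (camera adjusted p = 0.99, 0.79 and 0.89). The mean of the fibroblast markers was 0.02, of opposite sign to their median and to the direction of the test, which was down. The 3' minus 5' difference of the ACTB control probe sets, which rises as RNA degrades, was 1.29 ± 0.09 in vehicle and 1.09 ± 0.31 in SAH-BCL9B (SD, n = 3, exact permutation p = 0.4, two-sided). That of GAPDH was 0.16 ± 0.02 and 0.12 ± 0.03 (exact p = 0.2, two-sided), where the smallest p that 3 arrays against 3 can give is 0.1. Hybridization spikes read 12.1 ± 0.17 and 12.0 ± 0.09 (exact p = 0.7, two-sided), and poly-A spikes 9.04 ± 0.28 and 8.71 ± 0.14 (exact p = 0.2, two-sided).

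The first principal component, with 43.4% of the variance, separated the groups: vehicle arrays lay between -18.2 and -13.3 and SAH-BCL9B arrays between 11.8 and 22.3. The second, with 30.2%, set vehicle 3 (-15) and SAH-BCL9B 2 (-19.9) apart from the other 4 arrays (2.8 to 15.2). These same 2 arrays had the smallest SD of log2 values, 2.43 and 2.42, against 2.47 to 2.49 in the others, and SAH-BCL9B 2 had the lowest ACTB 3' minus 5' difference, 0.735. With both arrays left out, 1194 genes passed, 959 of them among the 1370, and 14 G2/M genes, 11 genes of the unfolded protein response and ATF4 and 7 Wnt targets fell. In the same fit, 6 heat shock, 7 sterol, 7 lysosome, 7 inflammatory, 6 metallothionein and 6 histone genes rose.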

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

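Signals outside the gene-level comparison were looked for in probe sets that it did not use. Of 11721 probe sets unnamed here, 56 were raised and 67 lowered by SAH-BCL9B in limma's test of every probe set by itself, with log2 changes of up to 1.67 and down to -1.66. Of 1801 probe sets assigned to several genes, 34 were raised and 27 lowered. The largest rise among these, 2.37, was at a probe set assigned to 5 genes, and the largest fall was -1.58. A signal in probe sets that the gene-level comparison left out is why these are listed. None of them was named, and no explanation was tested.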

How the results depend on the processing

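The covariate fits and the fit without vehicle 3 and SAH-BCL9B 2 were chosen after seeing the data. Of 12 list medians past the set test, none changed sign in any alternative, and 11 kept their call in all fits with the preset correlation and with fry; the exception was the G1/S list. With an estimated correlation 0 lists passed, the Wnt target list included (median -0.18, adjusted p = 0.12; its medians over the alternatives ran from -0.219 to -0.121 and its adjusted p from 3.6e-06 to 0.12). Among named genes, 1198 values kept direction and call, 132 lost the call, 9 gained one, and 1 turned sign: CCND1, -0.02 with the mean of all probe sets, which averages 2 probe sets of opposite sign. The median log2 change of all genes was 0.0183 with median centring and 0.0127 with a second quantile normalization, against 0.0195. The deposited arrays were already alike in distribution, so these fits could hardly move it and decide nothing. The counts of genes changed by SAH-BCL9B, genes raised by SAH-BCL9B and genes lowered by SAH-BCL9B (1370, 691 and 679) became 2456, 1381 and 1075 with a variance trend and robust fit, 2172, 1114 and 1058 with array weights, and 2440, 1286 and 1154 with array SD as a covariate. With the filter on low values 2272 genes passed, 1260 of them raised, 1283 of them among the 1370. The cause of these increases was not tested. Testing every probe set by itself gave 769 changes of at least 1.5-fold against 405; the first counts probe sets and the second genes, so the counts do not compare. Leaving out 1 array gave 316 to 1426 changed, 107 to 699 raised and 209 to 727 lowered genes, lowest without vehicle 1 and highest without SAH-BCL9B 2. Fewer arrays leave less power, which does not account for the rise to 1426, whose cause was not tested. With the replicate number as a block, 296 genes passed, 101 raised and 195 lowered, all 296 among the 1370. Of the named genes, 21 lost the call in this fit, AXIN2 among them (limma adjusted p = 0.11). CD44 (0.058), ASCL2 (0.055), H2BC4 (0.063), ENPEP (0.078), MUC13 (0.055) and NQO1 (0.054) were others. Arrays that share a number did not deviate together (correlations of 0.24, -0.2 and -0.32), and 2 of 6 correlated best with their own number. These values show no pairing by number, but so few arrays cannot exclude it. The fit with the block is therefore not set aside. Signal over background was not used here, so its limit on dim genes is unknown.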

Other observations

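The added lists, the covariate fits and the Wnt list without shared members were chosen after the changes of the comparison had been seen, and the test of G2/M against G1/S after its own values were. Genes of amino acid supply and tRNA charging were lower in SAH-BCL9B. Without PCK2 and NUPR1, which had prompted the list, 16 of 19 measured members fell and none rose (median log2 change -0.526, limma's camera adjusted p = 8.7e-19 over 7 such lists, adjusted p = 0.0256 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, changed by -1.12 ± 0.08 (SE, limma adjusted p = 0.00071), the alanyl-tRNA synthetase gene AARS1 by -0.97 ± 0.11, the amino acid transporter gene SLC7A5 by -0.95 ± 0.07 and MTHFD2, of mitochondrial folate metabolism, by -0.71 ± 0.08. The number that fell was 7 without vehicle 1, 8 without vehicle 2, 9 without SAH-BCL9B 1 or SAH-BCL9B 3 and 10 without vehicle 3. Together with the ATF4-linked genes of the report, which were split off after their values were seen, this raises the hypothesis of a lower amino acid response. No control peptide was used, so a link to BCL9 was not tested.

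Subunits of the V-ATPase were higher. Apart from ATP6V1C2 and from ATP6V0D1 and ATP6V1H, which the fixed lysosome list holds (0.43 and 0.23), all 15 measured subunits and accessory proteins in the list had a positive change (median 0.39, limma's camera adjusted p = 3.9e-08), 6 rose and none fell, with ATP6V0A2, for which 2 of 6 probe sets went the opposite way, at 0.62 ± 0.09 and ATP6V0B at 0.54 ± 0.09 (SE). The adjusted p was 0.0497 with an estimated correlation. The number that rose was 1 without vehicle 1 or SAH-BCL9B 1 and 3 without vehicle 2 or SAH-BCL9B 3. Histone genes outside the fixed list, without H2BC4 and H4C8, were higher as well (median 0.45, camera adjusted p = 0.0013, 5 of 10 raised, adjusted p = 0.0529 with an estimated correlation). H2BC9 and H2BC6 rose by 0.83 and 0.79, while H3-3A, H2AX and H2AZ1 had values of -0.23, -0.16 and -0.04 and did not pass. Histone genes share sequence, so single members are uncertain. Of the 10, 3 rose without vehicle 2, vehicle 3 or SAH-BCL9B 3. Both results are consistent with a rise beyond the genes that prompted each test, for the histones in part of the class only.

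Other hypotheses found less. ID1 fell with ID3, by 1.61 on the log2 scale (limma adjusted p = 0.000574), and both are known to respond to BMP signals. The other 19 measured genes of the BMP and TGF-beta response, without ID1, ID3 and 3 further genes seen before, had a median of -0.054 (SE over arrays 0.034, limma's camera adjusted p = 0.41), with 8 positive and 11 negative changes. The criterion written beforehand counted a median above -0.10, or a list that missed the set test, against a lower response, and both were met, the median by more than its SE, so these 19 genes count against it. They do not exclude it, a reading chosen after the value was seen, because the list left out ID1, ID3, TGFB2, SKIL and SMAD9, which all fell. No such member was left out of the list that follows. A rise of lipid synthesis as a whole is argued against: 15 genes of fatty acid synthesis had a median of 0.024 (SE 0.045, camera adjusted p = 0.64) against 0.31 for the sterol genes. Their mean was -0.003 and the test's direction down, of opposite sign to the median, and SREBF1 fell by 0.63 (adjusted p = 0.008). Glycolysis genes had a median of 0.048 and negative regulators of the cell cycle one of 0.064 (camera adjusted p = 0.64 for both), with 1 gene raised in each, SLC2A1 and KLF6, both lost without vehicle 1; 3 of these regulators rose without SAH-BCL9B 2.

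The fall of G2/M and mitosis genes was weighed against 2 other explanations. With the SD of each array's values as a covariate the list median was -0.423, but the SD differed by only 0.004 ± 0.025 (SE) between the groups, so this fit could hardly move a group difference and decides nothing. The other was fewer cycling cells in every phase, taken to lower G1/S genes by as much. The difference of the list means, G2/M minus G1/S, changed by -0.334 ± 0.015 (SE, exact permutation p = 0.1, two-sided, the smallest that 3 arrays against 3 can give). G2/M genes thus fell further, which was known when the test was chosen. Equal falls were assumed and not measured, so fewer cycling cells stay open. A change in cycle progression that bears more on G2/M may be a candidate explanation too, and no cell cycle distribution was measured here.

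Sterol, lysosome and heat shock genes were higher as lists in the camera test, and none of the 3 lists passed with an estimated correlation (adjusted p = 0.083, 0.16 and 0.08). With the ACTB 3' minus 5' difference as a covariate, the median over the members of the 3 lists was 0.309. That difference changed by -0.206 ± 0.187 (SE) between the groups. It rested largely on SAH-BCL9B 2, at 0.735 against 1.197 to 1.382 in the other arrays. The fit therefore leans on 1 array and does not decide on RNA integrity. With array SD as a covariate the median over the members was 0.304, which decides nothing, as the SD was balanced between the groups. A response of the cells to a peptide of this kind, whatever its sequence, may account for it, and so may the loss of BCL9 binding. The design has no control peptide, and neither was tested.

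The fall of the Wnt targets may rest in part on genes of other processes. Without 4 members, VEGFA, CD44 and MYC, which other lists also hold, and the mitotic gene BIRC5, the median of the remaining 23 was -0.133 (SE over arrays 0.058, limma's camera p = 0.00013, p = 0.046 with an estimated correlation), 4 fell and 16 changes were negative. The criterion written beforehand counted a median below -0.10 with a passed set test against a share of other processes. Both were met, which counts against that explanation. Yet the median lay below -0.10 by less than its SE, a demand that the written criterion did not hold. On that stricter reading the share of other processes cannot be told apart from a fall of the pathway. With array SD, balanced between the groups, as a covariate, the median of the whole list was -0.171, which decides nothing. Lower activity of beta-catenin stays open, beside a general response to the peptide, which was not tested.

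The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone, 1 of 10, gave as many changed genes (1370, highest other 0), as many changed at least 1.5-fold (405, highest other 0) and as many lists past the set test (12, highest other 6). The other splits, which mix vehicle and SAH-BCL9B arrays, still gave 3 to 6 lists past the set test with 0 changed genes. The sides of each such split hold unequal numbers of vehicle arrays, so part of the treatment difference remains between them. The rest adds to the spread within the sides, which makes single genes harder to call. Neither count shows what the tests give without a difference, so the 12 lists cannot be gauged by it. With an estimated correlation none of the 12 passed.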
